A study of Mus musculus with 4 samples.

How the data were processed

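RNA was sequenced from 4 libraries of mouse embryonic stem cells, 2 titled DMSO and 2 titled as cytarabine treated. Per the labels' protocols, cells were flash frozen, RNA was extracted with Trizol, and libraries were built from 1 ug of total RNA with an Illumina TruSeq RNA kit. HISAT2 and featureCounts, and the builds mm8 and mm10, are listed with no role or version, per the submitters' processing notes. Which build each table used, the annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here.

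The authors deposited a table of raw counts for 32245 gene symbols, whole numbers whose totals differ between libraries. A second deposited table holds estimated counts for 301 repeat names, of which 45.2% to 49.8% per library are not whole numbers, so reads appear to have been shared between repeats by a rule not given in the sources used here. These expected counts were rounded to whole numbers before any test. Repeat counts came to 381243 and 414910 in the DMSO libraries and 464081 and 433831 in the cytarabine libraries after rounding. Column names show the group but no replicate number, so columns were assigned to groups and not to numbered replicates.

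The tables do not place genes in the genome. Coordinates and gene types came from GENCODE's mouse release M21 for GRCm38 (mm10), matched by symbol for 31490 of the 32245 symbols. They are 1-based.

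The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined, except where stated otherwise. Gene counts were scaled by TMM factors and filtered with filterByExpr (minimum count 10, minimum total 15), which left 17644 genes. They were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, cytarabine against DMSO with no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. Repeats used the library sizes and factors of the gene table, and 241 passed the filter. Standard errors are the absolute log2 fold change divided by the square root of the F statistic, and CPM values use the scaled library sizes. The log2 ratios within a pair used CPM with a prior count of 2. A fold against a group at 0 counts is given as a bound against 3 counts over the group.

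Of 26 fixed lists, 25 had members tested and were tested with camera (limma 3.58.1, two-sided) on log2 CPM with a preset correlation of 0.01, adjusted over the lists. Of these, 18 were called, 17 with the pair as a block, and 0 with an estimated correlation. With fry, which asks whether a list moves on balance 1 way, 0 of the lists were called at the adjusted threshold. Counts adjusted over the list alone use the same p-values.

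Named genes were Dux, Zscan4c, Zscan4d, Zfp352, Cdkn1a, Mdm2, Pou5f1, Nanog and Sox2 whatever their values. To these were added the 8 higher and 8 lower genes with the largest log2 fold change among those with an adjusted p under 0.05, a mean count of at least 50 and both cytarabine libraries on the same side of both DMSO libraries. Up to 3 called members per list with the smallest adjusted p completed them. For repeats the rule named MERVL-int and MT2_Mm, and up to 5 called elements per direction with a mean count of at least 50. Neither name is in the table and 0 elements were called, so MERVL and MERVL_LTR are reported as the members of the fixed MERVL list.

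Codes in the column names join 1 DMSO and 1 cytarabine library into each of 2 pairs. The correlation of deviations from the group means within a pair was 0.590, and the second principal component (28.7% of the variance, against 64.3% for the first, which separates the treatments) separated the pairs. Pair was therefore treated as a batch found in the file, blocked values stand beside the main ones, and the labels do not say what the codes mark. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 35.5 in DMSO and 45.3 in cytarabine, so none was counted as a duplicate. In pair 2 all genes that the annotation places on unplaced scaffolds were at 0, and none of these is among the named genes.

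Alternatives were RLE and upper-quartile factors, library size alone, no filter, a minimum of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, thresholds of 0.01 or 2-fold, repeats scaled by their own factors, and leaving out each library. The block, DESeq2 with the block, and runs without scaffold or mitochondrially encoded genes were added after seeing the data. Scripts were tested on simulated counts. Without a block, 11% of genes changed 2-fold and 66% of those changed 4-fold were recovered among 17199 genes, with 12 of 89 calls false. With the block the shares were 80% and 97% among 17193 genes, with 28 of 205 calls false. For repeats, 83.3% of elements changed 4-fold were recovered among 229 without the block and 95% among 236 with it. The simulated sets tested with and without the block differ in size, so these shares do not compare the models on the same data. In both gene runs the share of false calls was above the adjusted p threshold. Each gene run changed 100 genes 2-fold and 100 genes 4-fold, far fewer than the 2983 genes called in the real libraries. The run without the block also held no pair effect. The shares recovered and falsely called therefore need not carry over. The calls on the real libraries, with or without the block, may still hold an excess of false ones, whose size these runs do not give.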

Results

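Gene and repeat expression was measured by RNA sequencing in 4 libraries of mouse embryonic stem cells of the C57BL/6 strain. The titles name 2 control libraries treated with DMSO, the solvent control, and 2 libraries treated with cytarabine, a nucleoside analogue that blocks DNA synthesis, and the labels give 24 h of treatment. The treatment field calls the controls untreated, and the treatment protocol speaks of a single treated replicate, while the titles and the treatment field give 2. Total counts over genes were 33835389 and 34592926 in the DMSO libraries and 36451020 and 35670843 in the cytarabine libraries. The column names carry codes that join each DMSO library to 1 cytarabine library, and these are called pair 1 and pair 2. Nothing in the labels says that the libraries came from separate cultures. The p-values therefore measure only the spread between these libraries, part of which may be technical. Sampling noise alone is argued against by a chi-square per degree of freedom of 35.5 in DMSO and 45.3 in cytarabine. With treatment in the model, 1354 genes were higher and 1104 lower in pair 2.

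The comparison of cytarabine with DMSO asks how gene expression responds to the drug, in a series whose title concerns entry into and exit from the 2C state. That state is a rare condition of embryonic stem cells in which genes of the 2-cell embryo are active. Genes of the 2C-like state, targets of the tumour suppressor p53 and the basement membrane genes Col4a1, Col4a2 and Lamb1 were among those that rose. Pluripotency factors, mitotic genes, ribosomal protein genes, the replication helicase gene Mcm3 and the serine synthesis gene Psat1 were among those that fell. In edgeR's quasi-likelihood test, 1304 of 17644 genes were higher and 1679 lower with cytarabine at the adjusted p threshold of 0.05. With the pair as a block these counts were 4562 and 4422, and all 2983 genes called without the block were called with it. Each of those 2983 genes had the same sign in both pairs, against 84.2% of all 17644 tested genes. The calls were made on these same 4 libraries, so the shared sign is not a replication. The scaling moved the split: 43.7% of the calls were higher with the main TMM factors, 58.6% with upper-quartile factors and 78.4% with library size alone, which moved the median log2 fold change over genes by 0.12 and 0.28. Leaving out either cytarabine library left 0 genes called in either direction by edgeR, with 1971 higher and 2304 lower at an unadjusted p under 0.05 without that of pair 1, and 1652 and 2425 without that of pair 2. Without the DMSO library of pair 1 the counts were 513 and 444, and without that of pair 2 they were 389 and 263. Of 73 named genes and elements, 68 had a call in the main test, and all of these lost it without the cytarabine library of either pair. Some also lost it without the DMSO library of pair 1, and more without that of pair 2. Without either cytarabine library edgeR called 0 members of each list.

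**Figure D1:**
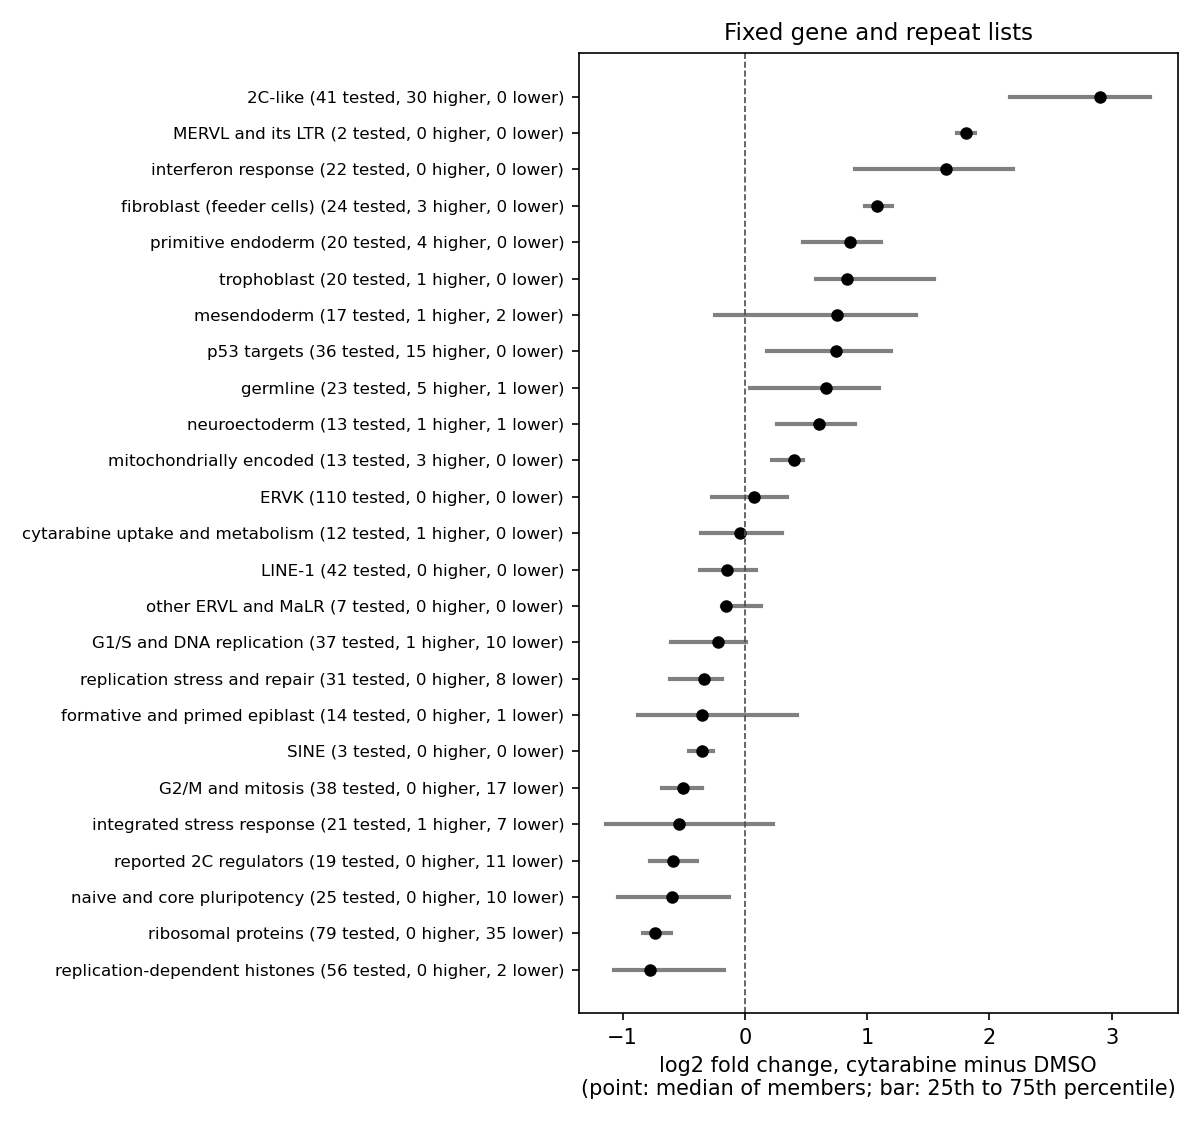
Each point is the median log2 fold change (cytarabine minus DMSO, edgeR) of the tested members of a list fixed before the data were examined, with a bar from the 25th to the 75th percentile; the labels give the members tested and those called higher or lower at an adjusted p of 0.05. The 2C-like list has the highest median, 2.91, and the replication-dependent histones the lowest, -0.78; the medians of the G1/S, LINE-1 and other ERVL lists turn positive, and that of the cytarabine metabolism list does too, when libraries are scaled by their total counts alone.

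Genes of the 2C-like state rose with cytarabine: 30 of 41 tested members passed the test and none fell. Zfp352, a zinc finger gene of the 2-cell embryo, went from 0.418 ± 0.134 to 4.20 ± 0.0451 CPM (counts scaled by library size; mean ± SD, n = 2 per group), a log2 fold change of 3.32 (SE 0.455, adjusted p = 0.0235). The deubiquitinase gene Usp17lb went from 2.30 ± 0.557 to 22.5 ± 0.109 CPM, and the PRAME family genes Gm13119 and Pramef25 rose by log2 fold changes of 3.36 and 3.07. Duxf3, the Dux gene whose product activates the 2-cell programme, rose with a log2 fold change of 3.44 (SE 0.810, adjusted p = 0.0488), but its cytarabine libraries stood apart at 3.01 CPM in pair 1 and 13.4 CPM in pair 2. Its call was lost with limma-voom, with upper-quartile factors and without any 1 of the 4 libraries, where its log2 fold change ranged from 1.97 without the cytarabine library of pair 2 to 4.15 without that of pair 1. Zscan4c, which lies with Zscan4d in a cluster on chromosome 7 and serves as a marker of the state, stood at 51.3 ± 34.4 CPM in DMSO and 185 ± 9.49 CPM in cytarabine (log2 fold change 1.85, adjusted p = 0.0589). Zscan4d stood at 17.6 ± 11.9 and 67.9 ± 6.50 CPM (log2 fold change 1.95, adjusted p = 0.0553). Neither passed the main threshold, and both passed with the pair as a block (adjusted p = 9.7e-05 and 6.6e-05).

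Of the 2C-like list, 40 members were higher when adjusted over the list alone and 41 with the pair as a block, and all 41 were above 0 in both pairs. The median log2 fold change was 2.91. The list stood above other genes by camera with a preset correlation (adjusted p = 5.58e-14), but adjusted p = 0.556 with an estimated correlation, and fry gave an adjusted p of 0.0688. Leaving out either cytarabine library left 0 members called by edgeR, with 36 called without the DMSO library of pair 1 and 28 without that of pair 2, while the camera adjusted p ranged from 1.81e-21 to 6.34e-11 with 1 library left out. The Zscan4, Usp17l, Tdpoz, Tcstv and Dux genes and several unnamed members belong to multicopy families, so the values of single copies are uncertain. Summed over 5 copies, the Zscan4 family stood at 210 ± 143 CPM in DMSO and 748 ± 37.7 CPM in cytarabine (n = 2 each). In the annotation of the mm10 build, Duxf3 lies on chromosome 10 at 58229979 to 58232675, Zfp352 on chromosome 4 at 90218820 to 90225702, Zscan4c on chromosome 7 at 11005745 to 11010547 and Zscan4d on the same chromosome at 11161374 to 11166159, all annotated as protein-coding genes.

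**Figure D2:**
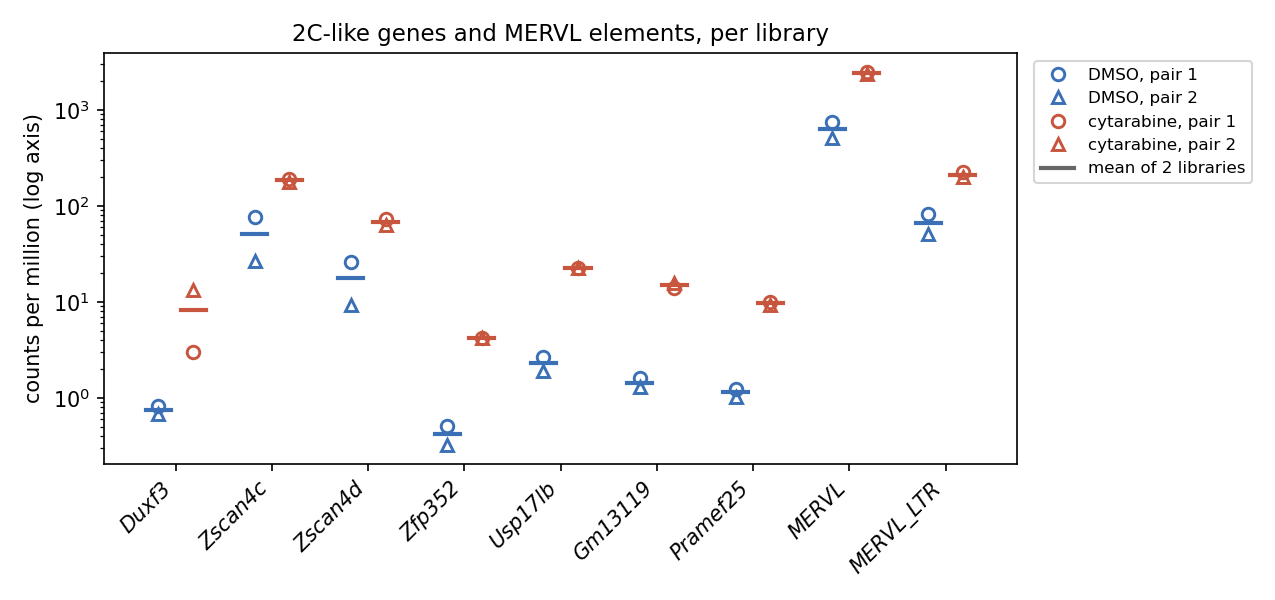
CPM on a log axis for 7 genes of the 2C-like list and 2 MERVL elements; circles are the libraries of pair 1, triangles those of pair 2, and bars the mean of the 2 libraries of a group. Each of the cytarabine libraries lies above both DMSO libraries for every gene and element shown, with MERVL at 627 CPM in DMSO and 2431 CPM in cytarabine on average; the MERVL elements and the Zscan4 genes shown passed with the pair as a block and not in the main test.

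Retrotransposon transcripts of the MERVL family, which are expressed in the 2-cell embryo, had higher mean levels with cytarabine but did not pass the main test. MERVL stood at 627 ± 164 CPM in DMSO and 2431 ± 94.7 CPM in cytarabine (n = 2 each; log2 fold change 1.96, SE 0.381, adjusted p = 0.158). The LTR of the same family, MERVL_LTR, stood at 66.7 ± 21.4 and 212 ± 18.9 CPM (log2 fold change 1.67, SE 0.335, adjusted p = 0.158). With the pair as a block both passed (log2 fold changes 1.98 and 1.70, adjusted p = 0.0299 and 0.0402). As a share of all repeat counts, MERVL made up 6.07% (95% exact binomial interval 6.00 to 6.15) and 3.81% (3.75 to 3.87) in the DMSO libraries of pair 1 and pair 2, and 22.0% (21.9 to 22.1) and 21.0% (20.9 to 21.1) in the cytarabine libraries. These intervals cover counting error only.

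Over the repeat table, edgeR called 0 of 241 elements in either direction, while 14 higher and 5 lower elements had an unadjusted p under 0.05. DESeq2 called 4 elements higher and 0 lower, limma-voom 0 (20 at an unadjusted p under 0.05) and edgeR with the block the 2 MERVL elements. Without the DMSO library of pair 1 edgeR called 6, and without any other library 0. The other 2 that DESeq2 called were RLTR6B_Mm and ERVB4_2-I_MM, named here after their values were seen. The MERVL list had both members called when adjusted over the list alone (camera adjusted p = 2.8e-04; adjusted p = 0.440 with an estimated correlation). LINE-1 elements had a median log2 fold change of -0.15 over 42 elements with 0 called, also 0 adjusted over the list alone (camera adjusted p = 0.00818; adjusted p = 0.599 with an estimated correlation), and their median was 0.12 with library size alone. The LINE-1 camera call was lost without the DMSO library of pair 2 (0.0585) and the cytarabine library of pair 1 (0.0760). The ERVK list (110 elements, median 0.08, camera adjusted p = 0.973), the other ERVL and MaLR elements (7, median -0.15, adjusted p = 0.520) and the SINE elements (3, median -0.35, adjusted p = 0.114) had 0 members called by edgeR, over all elements or adjusted over the list alone. At an unadjusted p under 0.05 there were 6 ERVK elements higher and 3 lower, 2 LINE-1 elements lower, both MERVL elements higher and 0 among the SINE and the other ERVL and MaLR elements. DESeq2 called 1 ERVK element and limma-voom 0, and with DESeq2 and the block 5 ERVK and 6 LINE-1 elements were lower. The median and the camera direction of the ERVK list differed in sign, and the median of the other ERVL and MaLR elements was 0.13 with library size alone. With repeats scaled by their own factors, 1 of the 5 repeat lists gained a camera call. No satellite name matched in the repeat table.

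Reported repressors and regulators of the 2C state fell: 11 of 19 tested members were lower and none higher (14 lower adjusted over the list alone; 17 lower and 1 higher with the block). Rif1, a replication timing and heterochromatin factor, went from 524 ± 43.1 to 234 ± 20.9 CPM (n = 2 each; log2 fold change -1.16, SE 0.129, adjusted p = 0.0223). The lower members were 5, with 1 higher, under library size alone, 6 with upper-quartile factors and 4 without the DMSO library of either pair. Trim28, a co-repressor of retrotransposons, fell from 2502 ± 138 to 1243 ± 39.6 CPM, and Kdm1a, a histone demethylase gene, from 366 ± 15.3 to 194 ± 1.19 CPM. The median log2 fold change of the list was -0.59 (camera adjusted p = 2.0e-05; adjusted p = 0.440 with an estimated correlation).

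Targets of p53 rose in 15 of 36 tested members and fell in none (17 higher adjusted over the list alone; 24 higher and 4 lower with the block). Mdm2, the ubiquitin ligase that restrains p53, went from 201 ± 0.532 to 460 ± 22.4 CPM (n = 2 each; log2 fold change 1.19, SE 0.106, adjusted p = 0.0223). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 122 ± 8.20 to 230 ± 34.7 CPM (log2 fold change 0.91, SE 0.147, adjusted p = 0.0280). Btg2 and Ddit4l rose by log2 fold changes of 1.79 and 1.93. Without the DMSO library of either pair 8 members were higher, and with library size alone 20. The list median was 0.74 (camera adjusted p = 2.5e-04; adjusted p = 0.440 with an estimated correlation). Cdkn1a and this median lay below the median of the list of fibroblast markers, 1.08, while Mdm2, Btg2 and Ddit4l lay above it. In which cells the p53 targets rose was not tested. Mdm2 lies on chromosome 10 at 117688875 to 117710758 and Cdkn1a on chromosome 17 at 29090976 to 29100727.

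Genes of mitosis and DNA replication fell in part. Of 38 G2/M genes, 17 were lower and none higher (27 lower adjusted over the list alone; 31 lower and 1 higher with the block), among them the kinase gene Plk1 (256 ± 17.4 to 99.2 ± 18.4 CPM, log2 fold change -1.36), Ect2 (-1.04) and the spindle motor gene Kif11 (-0.90). With library size alone 5 G2/M genes were lower, with upper-quartile factors 9, and without the DMSO library of pair 1 or pair 2 they were 4 and 3. The G2/M median was -0.51 (camera adjusted p = 3.57e-08; adjusted p = 0.440 with an estimated correlation). Of 37 G1/S and replication genes, 10 fell and 1 rose (13 and 1 adjusted over the list alone; 17 and 2 with the block). The replication helicase subunit Mcm3 went from 585 ± 21.6 to 321 ± 9.46 CPM, and Rfc4 and Gins1 had log2 fold changes of -1.20 and -1.17. The lower G1/S genes were 6 with library size alone, 8 with upper-quartile factors, and 4 and 2 without the DMSO library of pair 1 or pair 2. The G1/S median of -0.22 was 0.06 with library size alone, where it was -0.28 relative to the median of all genes (camera adjusted p = 0.00220; adjusted p = 0.599 with an estimated correlation).

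Among 31 replication stress and repair genes, 8 fell and none rose (11 lower adjusted over the list alone; 18 lower and 1 higher with the block). H2afx, whose histone product is phosphorylated at DNA breaks, went from 388 ± 17.1 to 82.2 ± 19.8 CPM (n = 2 each; log2 fold change -2.24, SE 0.196, adjusted p = 0.0223), and the checkpoint genes Atr and Hus1 had log2 fold changes of -0.90 and -1.13. With library size alone and with upper-quartile factors 3 members were lower, and without the DMSO library of pair 1 or pair 2 they were 3 and 1. The list median was -0.33 (camera adjusted p = 1.8e-04; adjusted p = 0.440 with an estimated correlation). Replication-dependent histone genes had 2 of 56 members called lower, Hist3h2ba and Hist1h2ae, 0 adjusted over the list alone (10 lower at an unadjusted p under 0.05, 4 by DESeq2 and 2 by limma-voom) and 20 with the block. Their median was -0.78 (camera adjusted p = 4.0e-05; adjusted p = 0.599 with an estimated correlation), and both of those calls were lost with library size alone, with upper-quartile factors and without any 1 library. Most of these transcripts lack poly(A) tails and the genes form a multicopy family, so their counts are uncertain.

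Pluripotency genes fell in 10 of 25 tested members and rose in none (15 lower adjusted over the list alone; 16 lower with the block). The lower members were 5 with library size alone, 8 with upper-quartile factors and 7 without the DMSO library of either pair. Pou5f1, which encodes the factor Oct4, went from 755 ± 115 to 380 ± 95.8 CPM (n = 2 each; log2 fold change -0.99, SE 0.218, adjusted p = 0.0432). Sox2 fell from 388 ± 81.7 to 202 ± 24.5 CPM (log2 fold change -0.94, SE 0.188, adjusted p = 0.0368), and Lin28a, Zfp42 and Esrrb had log2 fold changes of -1.50, -1.23 and -1.19. With library size alone Pou5f1 and Sox2 kept their sign at -0.72 and -0.67 and were not called. The call of Pou5f1 was lost without any 1 library (log2 fold changes -1.29 to -0.75), and that of Sox2 without any but the DMSO library of pair 1 (-1.09 to -0.72). Nanog did not pass the test, at 399 ± 82.4 and 411 ± 108 CPM (log2 fold change 0.04, SE 0.239, adjusted p = 0.909), and its log2 ratio was -0.45 in pair 1 and 0.52 in pair 2. The list median was -0.60 (camera adjusted p = 5.2e-05; adjusted p = 0.440 with an estimated correlation). Pou5f1 lies on chromosome 17 at 35506018 to 35510772, Sox2 on chromosome 3 at 34650405 to 34652461 and Nanog on chromosome 6 at 122707489 to 122714633. Fibroblast markers moved the other way in the same libraries, with a median log2 fold change of 1.08 over 24 genes.

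**Figure D3:**
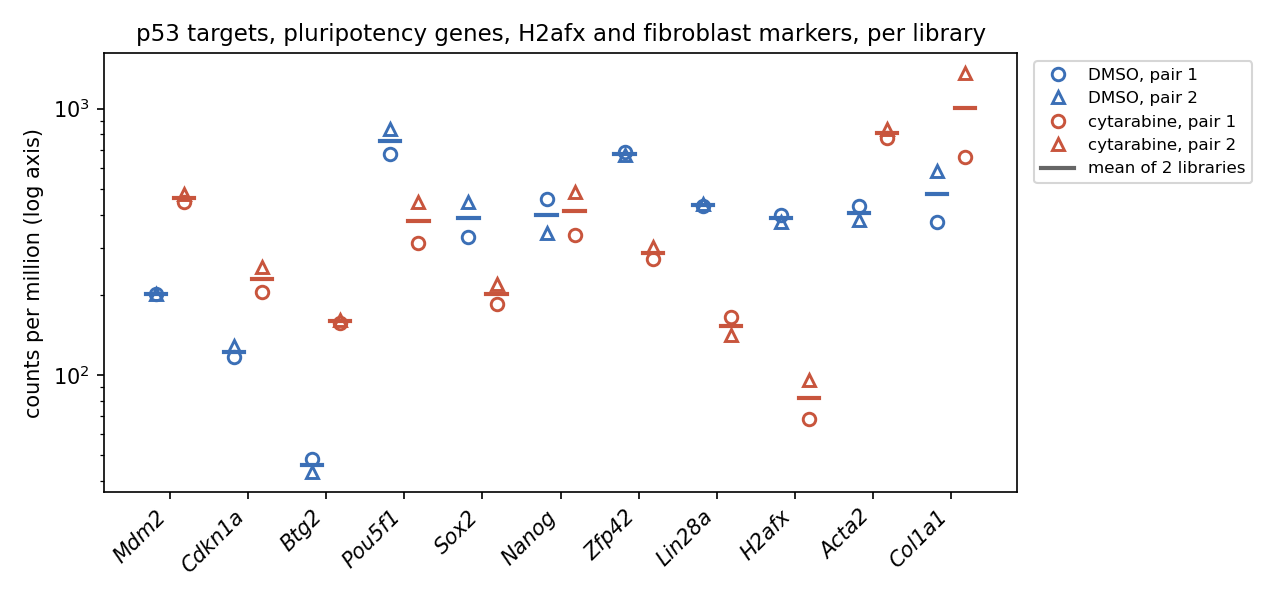
CPM on a log axis for 3 p53 targets, 5 pluripotency genes, H2afx and 2 fibroblast markers; circles are the libraries of pair 1, triangles those of pair 2, and bars the mean of the 2 libraries of a group. Mdm2 is at 201 CPM in DMSO and 460 CPM in cytarabine on average and Pou5f1 at 755 and 380 CPM, while the Nanog libraries of the groups overlap; Col1a1 passed with the pair as a block and not in the main test.

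Markers of other cell types had mostly positive log2 fold changes, and in which cells they rose was not tested. The primitive endoderm calls named below (0.85 to 0.92) lay near the median of the fibroblast list, 1.08. Of 24 fibroblast genes, a list meant to show feeder cells, 3 rose: Acta2 from 407 ± 34.2 to 807 ± 46.6 CPM (n = 2 each; log2 fold change 0.99, SE 0.123, adjusted p = 0.0223), Vim (0.65) and Twist1 (0.98). This was 2 adjusted over the list alone, 7 with library size alone, 2 and 0 without the DMSO library of pair 1 or pair 2, and 23 with the block (camera adjusted p = 4.0e-04; adjusted p = 0.599 with an estimated correlation). Col1a1, chosen after its values were seen, stood at 375 and 582 CPM in the DMSO libraries of pair 1 and pair 2 and at 655 and 1359 CPM in the cytarabine libraries. Primitive endoderm genes rose in 4 of 20 members (7 adjusted over the list alone; 10 higher and 1 lower with the block; 1 and 0 without the DMSO library of pair 1 or pair 2), led by the basement membrane genes Lamb1 (0.85), Col4a1 (0.88) and Col4a2 (0.92), with a median of 0.86 (camera adjusted p = 0.00818; adjusted p = 0.468 with an estimated correlation). Of 20 trophoblast genes Rhox9 alone rose (log2 fold change 1.51), 0 adjusted over the list alone (4 at an unadjusted p under 0.05, 4 by DESeq2 and 1 by limma-voom) and 14 with the block (median 0.84, camera adjusted p = 0.0212; adjusted p = 0.599 with an estimated correlation). The camera call was lost without the DMSO library of pair 2 (adjusted p = 0.102 for primitive endoderm and 0.244 for trophoblast), and for trophoblast without the cytarabine library of pair 1 (0.180) and with library size alone (0.0789).

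Among 17 mesendoderm genes Nodal, a ligand of the TGF-beta family, rose (65.1 ± 10.2 to 184 ± 71.5 CPM, log2 fold change 1.50), while Lefty1 and Lefty2, which encode Nodal antagonists, fell (-1.30 and -1.11). The Nodal call was lost without any 1 library, both Lefty calls with library size alone, and that of Lefty2 also with upper-quartile factors. These were also the calls adjusted over the list alone, with 6 higher and 3 lower with the block (median 0.75, camera adjusted p = 0.591). The neuroectoderm list of 13 genes had 1 higher and 1 lower (2 and 1 adjusted over the list alone; 5 and 3 with the block; median 0.60, camera adjusted p = 0.331). Its member Stmn2 fell from 277 ± 40.0 to 116 ± 1.57 CPM, and Neurog2, at 0 counts in both DMSO libraries and 0.441 CPM in cytarabine, was at least 9.13-fold higher against 3 counts over the group. The Neurog2 call was lost without any 1 library. Formative and primed epiblast genes had 1 of 14 lower, Pou3f1 (-0.88), with 3 lower adjusted over the list alone and 4 higher and 8 lower with the block (median -0.35, camera adjusted p = 0.157). The Pou3f1 call was lost without the DMSO library of pair 2 and without either cytarabine library.

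Germline genes rose in 5 of 23 members and fell in 1 (6 and 1 adjusted over the list alone; 12 and 5 with the block). Without the DMSO library of pair 1 or pair 2 the higher members were 1 and 2. Taf7l and Tex19.1 rose with log2 fold changes of 1.99 and 1.05, and the cohesin gene Stag3 fell (-0.77), a call lost with library size alone and without any 1 library. The germline median was 0.66 (camera adjusted p = 0.0272, 0.0736 with the block; adjusted p = 0.440 with an estimated correlation). That call was lost without the DMSO library of pair 1 (0.158) and without the cytarabine library of pair 2 (0.0559), with library size alone (0.0872) and without a low-count filter (0.0552). Of 22 interferon response genes 0 were called by edgeR, over all genes or adjusted over the list alone, and 18 higher and 1 lower with the block. At an unadjusted p under 0.05 there were 4 higher, and DESeq2 called 4 and limma-voom 0. Their median was 1.64 (camera adjusted p = 0.0250; adjusted p = 0.719 with an estimated correlation). The interferon call was lost without the DMSO library of pair 1 (0.419), without the cytarabine library of pair 2 (0.640), with library size alone (0.123) and with upper-quartile factors (0.0514).

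Genes of the integrated stress response, the ATF4 pathway that answers amino acid shortage, fell in 7 of 21 members and rose in 1 (9 and 1 adjusted over the list alone; 10 and 4 with the block). Psat1, an enzyme of serine synthesis, went from 494 ± 25.9 to 167 ± 6.00 CPM (n = 2 each; log2 fold change -1.56, SE 0.111, adjusted p = 0.0223), the mitochondrial folate enzyme gene Mthfd2 from 156 ± 22.0 to 71.1 ± 0.937 CPM, and Chac1, an ATF4 target, from 24.5 ± 6.89 to 4.09 ± 1.07 CPM. Without the DMSO library of pair 1 or pair 2 the lower members were 6 and 3. The list median was -0.54 (camera adjusted p = 0.0201; adjusted p = 0.599 with an estimated correlation), and the camera call was lost without the cytarabine library of pair 1 (0.153) and with a minimum of 1 CPM (0.0670). Ribosomal protein genes fell in 35 of 79 members and rose in none (63 lower adjusted over the list alone; 76 with the block), among them Rpl3 (-1.02), Rpl6 (-0.88) and Rpl7l1 (-0.90). With library size alone 10 members were lower, with upper-quartile factors 20, and without the DMSO library of pair 1 or pair 2 they were 4 and 1. Their median was -0.73 (camera adjusted p = 2.2e-14; adjusted p = 0.599 with an estimated correlation), and they took 6.49 ± 0.352% of gene counts in DMSO and 4.71 ± 0.737% in cytarabine.

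Mitochondrially encoded genes rose in 3 of 13 members, mt-Nd6 (0.63), mt-Nd5 (0.63) and mt-Nd4l (0.52), with 4 adjusted over the list alone, 9 with library size alone, 0 without the DMSO library of either pair and 9 with the block. Their share of gene counts was 2.30 ± 0.00170% in DMSO and 3.32 ± 0.275% in cytarabine (n = 2 each), and the median log2 fold change was 0.40 (camera adjusted p = 0.0193; adjusted p = 0.599 with an estimated correlation). This camera call was lost without the DMSO library of pair 1 (0.182), the DMSO library of pair 2 (0.102) or the cytarabine library of pair 2 (0.0884). Among 12 genes of cytarabine uptake and metabolism, the nucleoside transporter gene Slc28a3 rose from 0.193 ± 0.136 to 2.28 ± 0.763 CPM (log2 fold change 3.54, adjusted p = 0.0369), also the single call adjusted over the list alone, with 4 higher and 4 lower with the block. With library size alone 2 members were higher, and DESeq2 called 1 higher and 2 lower. The Slc28a3 call was lost without the DMSO library of pair 2 and without either cytarabine library. Dck, the kinase that activates cytarabine, was chosen after its values were seen and did not pass the main test (log2 fold change 0.41, adjusted p = 0.136) but passed with the block (0.40, adjusted p = 0.0116). The list median was -0.04 and its mean 0.28, which differ in sign (camera adjusted p = 0.621).

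The 8 largest increases under the fixed rule included the secreted phospholipase gene Pla2g2f, at 0 counts in both DMSO libraries and 3.94 ± 0.357 CPM in cytarabine, at least 81.6-fold higher against 3 counts over the group. The epidermal keratin genes Krt5 and Krt15 rose by log2 fold changes of 5.74 and 4.84, Espnl by 5.56 and Rhox4a2 by 5.60. In the DMSO libraries of pair 1 and pair 2, Krt5 had 0 and 4 counts, Krt15 11 and 2, and Espnl 6 and 6. The sizes of these increases are therefore uncertain. Gm4565, Gm10696 and AF067063 had log2 fold changes of 6.37, 6.00 and 4.91, from at most 4 counts in each DMSO library. By summed counts, Gm4565 (2 counts in DMSO, 235 in cytarabine) was 91.9-fold higher (95% exact binomial interval 25.2 to 764) and Rhox4a2 (3 and 197 counts) 51.4-fold (17.3 to 251), intervals that cover counting error only and not the spread between libraries. Rhox4a2, Gm4565, Gm10696 and AF067063 have similar copies and their values are uncertain. The 8 largest decreases were Gm36816 (-2.68), Chac1 (-2.58), the linker histone gene H1f0 (67.6 ± 22.5 to 11.5 ± 3.85 CPM, -2.55), Tril (-2.53), the transcription factor gene Klf15 (-2.32), H2afx (-2.24), D130058E05Rik (-2.10) and Rnf165. Gm36816 is annotated as antisense, and whether the counting used strand is not given in the sources used here, so its value is uncertain. The calls of Gm36816 and Tril were lost with library size alone and with upper-quartile factors, that of Tril also with limma-voom, and that of Krt15 with limma-voom.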

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

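The tests of explanations in this part were chosen after the results were seen. Nanog had log2 ratios of opposite sign in the 2 pairs, -0.45 in pair 1 and 0.52 in pair 2; the difference between the pairs was not tested, since 4 libraries leave no spread to test it against. With 2 libraries per group, no library could be tested as lying far from the others of its group. Genes on unplaced scaffolds, which enter no list, summed to 360 CPM in the cytarabine library of pair 1 and 170 CPM in its DMSO library, with no replicate of that difference.

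Genes on unplaced scaffolds were at 0 counts in both libraries of pair 2. Of 66 such genes, 53 had counts in pair 1, among them AC149090.1 with 3375 and 8510 counts and Vamp7 with 571 and 640. Zeros by chance at the depth of pair 2 are argued against, since only 0.994% of chromosomal genes with a pair 1 count within 20% of the scaffold genes' were at 0 there. That the scaffolds were left out when pair 2 was processed stays open: 100% of the 41 scaffold genes with at least 10 counts in pair 1 were at 0 in pair 2, but this is how the pattern was found. No biological explanation was tested.

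Fibroblast markers were higher with cytarabine (3 of 24 passed the main test and 23 the test with the block) and 10 of 25 pluripotency genes were lower. Scaling as the cause of both is argued against, since the list medians differed by 1.57 on the log2 scale in pair 1 and 1.91 in pair 2 and 1 factor per library moves both lists alike. Dilution by other cells as the whole cause of the lower pluripotency genes could not be decided. Those genes moved apart, with an SD of their blocked log2 fold changes of 0.544 against a median SE of 0.0898. This argues against 1 common factor, but dilution can also give such a spread where other cells express some of these genes. A larger share of fibroblasts in the cytarabine libraries and a response of stem cells or fibroblasts to the drug cannot be told apart, since 23 of 24 markers were above 0 in both pairs with blocked log2 fold changes from 0.99 to 1.15 between the 25th and 75th percentiles, near 1 common factor, while the others spread further (SD 0.282, median SE 0.106), as in a drug response or where stem cells express some of the markers; Col1a1, Fn1 and Vim reach 1359, 3055 and 1066 CPM in the cytarabine library of pair 2. The DMSO libraries also hold counts for all 24 markers, none of which is in another list, and whether feeder cells were used is not given in the sources used here.

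The 2C-like genes were higher with cytarabine, 30 of 41 past the main threshold. Reads shared between near-identical copies as the whole cause are argued against by the summed counts of families, which moving reads between copies leaves unchanged. Over 5 copies each, the Zscan4, Usp17l and Tdpoz sums were 3.56-fold, 8.09-fold and 12.3-fold higher with cytarabine. The 5 members taken as single-copy (Zfp352, Tmem92, Arg2, Spz1 and Usp26) had a median log2 fold change of 3.32, which is the value of Zfp352. Of these, 3 passed the main test. Scaling moves all genes of a library alike and is argued against by the list's 25th percentile lying 1.60 (pair 1) and 2.86 (pair 2) above the median log2 ratio of all genes. Both the 2C-like and the fibroblast medians were larger in pair 2 (2C-like 2.28 in pair 1 and 3.31 in pair 2, fibroblast 0.86 and 1.16). A larger share of fibroblast RNA raises no gene by more than its own factor. The 2C-like 25th percentile lay 0.65 (pair 1) and 1.64 (pair 2) above the fibroblast 75th percentile. That percentile may lie below the factor where stem cells also express some of the markers, so the smaller margin in pair 1 is uncertain. A response of fibroblasts to the drug was not tested, and a larger share of 2C-like cells or higher expression per cell, as a response to cytarabine, remains a hypothesis, and bulk libraries do not separate these.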

How the results depend on the processing

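The pair block, DESeq2 with the block, and the runs without scaffold or mitochondrially encoded genes were chosen after the data were seen; the cause of each change below was not tested unless given. The columns carry no replicate numbers, so the planned block on the titles' numbers was not run, and the pair from the column codes stood in as the replicate block. Higher and lower gene counts (1304 and 1679) became 4562 and 4422 with the replicate block, 2292 and 2656 with DESeq2, and 3406 and 3826 with DESeq2 and the block. They became 2135 and 587 with library size alone, 1468 and 1037 with upper-quartile factors, 1034 and 398 at a minimum of 2-fold, and 0 and 0 at an adjusted p under 0.01, where edgeR's smallest adjusted p was 0.0223. Leaving out 1 library gave 0 to 513 higher and 0 to 444 lower genes, with fewer libraries to estimate the spread and the lone library of a group assumed to vary like the other group.

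Repeat elements called higher went from 0 to 2 with the block, 4 with DESeq2, 5 with DESeq2 and the block (with 11 lower), 4 with library size alone, 3 at 1 CPM, and 0 to 6 with 1 library left out. Members of the 2C-like list called higher ranged from 0 to 36 with 1 library left out, against 30. Its adjusted p was 0.556 with an estimated correlation, 0.567 with that and the block, and 0.0688 with fry. The medians of the G1/S and LINE-1 lists, both called by camera, turned positive with library size alone (0.06 and 0.12). Their camera directions did not turn there. Directions turned for results that never passed: the ERVK list (adjusted p 0.525 at 1 CPM, 0.788 and 0.784 with the block with and without an estimated correlation, 0.906 with fry, 0.965 with its own factors, 0.747 to 0.929 with 1 library left out), the mesendoderm list (0.938 with library size alone, 0.0633 to 0.809 with 1 library left out), the other ERVL and MaLR list (0.156 to 0.875) and Nanog (log2 fold change -0.28 to 0.29).

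Over all alternatives, named genes and elements kept direction and side of the threshold in 844 comparisons, lost the call in 216, gained it in 27 and reversed in 2. In the other lists these numbers were 272, 71, 1 and 10. The block ended no call of a named gene, and of the lists it ended that of germline. Depth limits genes near the filter minimum of 10 counts, and histone genes at a few CPM.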

Other observations

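The gene families and tests in this part were chosen after the data were seen, and no family was tested against other genes. Of 55 genes whose symbols begin with Eif, mostly translation initiation factors and their regulators, 29 fell and none rose (43 lower and 2 higher with the block; median -0.57, -0.29 with library size alone), among them Eif4a1 and Eif5a. Of 17 aminoacyl-tRNA synthetase genes 13 fell and none rose (16 with the block; median -0.90, -0.62 with library size alone), among them Tars, Vars and Yars.

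Of 23 keratin genes 6 rose and none fell, among them Krt13, Krt5 and Krt15, and 17 passed with the block (median 2.31). Krt8, Krt18 and Krt19 passed with the block (adjusted p = 7.3e-04, 0.00166 and 0.00399) and not in the main test (0.834, 0.761 and 0.635). Genes of the X-linked Rhox cluster, which are expressed in placenta and germ cells, rose in 3 of 16 members, and in 13 with the block (median 2.13). The cluster holds similar copies, so single genes are uncertain. A set of 109 genes had 0 counts in both DMSO libraries and at least 10 in each cytarabine library, and 0 genes showed the reverse. Genes with any count numbered 20373 and 20272 in the DMSO libraries and 22895 and 22405 in the cytarabine libraries of pair 1 and pair 2. Among 632 long intergenic RNA genes 8.70% were higher and 0.949% lower, against 7.55% and 10.4% of 15932 protein-coding genes. Of 523 antisense genes 3.63% were higher and 0.382% lower. With the block 157 and 49 of the long intergenic RNA genes were higher and lower. For protein-coding genes these counts were 4281 and 4284, and for antisense genes 55 and 19.

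With treatment in the model, 1354 of 17644 genes were higher and 1104 lower in pair 2 than in pair 1. Of 22 interferon response genes 19 were higher in pair 2, as were 16 of 24 fibroblast genes (1 lower), and the chemokine gene Ccl2 stood at 2.92 CPM in the DMSO library of pair 1 and 69.7 CPM in that of pair 2. Ribosomal protein genes were higher in pair 2 in 39 of 79 members and replication-dependent histones in 10 of 56, while 7 pluripotency genes were higher and 6 lower of 25. Trophoblast genes were lower in pair 2 in 10 of 20 members, and of 17 mesendoderm genes 10 were lower and 2 higher. Krt8 stood at 259 CPM in the DMSO library of pair 1 and 4.23 CPM in that of pair 2, and 403 and 11.9 CPM in the cytarabine libraries.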
